A study of Mus musculus with 12 samples.

How the data were processed

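Chromatin occupied by RNA polymerase II (Pol II) was profiled by ChIP-seq, immunoprecipitation followed by sequencing, in mouse embryonic stem cells (ESCs) grown on feeder fibroblasts, per the labels' protocols. The cells carried a floxed Htatsf1 gene and a Cre recombinase that is switched on by tamoxifen, so that tamoxifen starts deletion of HTATSF1, an RNA-binding protein, and ethanol serves as the control. The series has 12 libraries in 6 groups of 2: Pol II after ethanol or tamoxifen at 48 h, Pol II after ethanol or tamoxifen at 72 h, and input DNA, not immunoprecipitated, after ethanol or tamoxifen at 48 h. No input at 72 h was analysed here. The labels do not say whether the libraries of a group came from separate cultures, so the replicates may be technical. Groups were taken from the treatment, time and antibody given in the labels.

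The deposited values are a ratio per RefSeq transcript, a travelling ratio per the file headers and the name of the table. A travelling ratio divides Pol II density near the transcription start by density over the gene body, so a higher value means relatively more Pol II at the start. The windows around the start, the minimum signal, and the meaning of the normalization mark in the column names are not given in the sources used here. Bowtie, Picard 1.82 and the mouse genome build mm9 are named per the submitters' processing notes, with no role given. Per the file headers, each of the 6 columns merges the libraries of a group, so there is 1 deposited value per transcript and group. Neither a spread between replicates nor a sequencing depth can be had from such values, and no interval that needs read counts is given. The authors' merged values are therefore printed without SD or n.

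The table held 30849 transcript rows of 23298 gene symbols, and 4388 symbols had more than 1 row. In 813 rows every column was minus infinity. The first row of each symbol stood for the gene, because no signal level was there to choose by. Genes with a finite ratio above 0 in all 4 Pol II columns were kept, 21441 of them or 92.0%, and 1857 were left out. The input comparison used the 21432 of these that were also above 0 in both input columns. Symbols were used as deposited. For 22887 genes the accession was found in a RefSeq gene table of a later mouse assembly, which was used for names only, and genomic positions are not printed because the builds differ.

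For each gene the log2 of the tamoxifen ratio over the ethanol ratio was computed at each time, with no pseudocount. Medians over genes are given with a 95% order-statistic interval. This interval describes the scatter over genes, which are not independent replicates, and says nothing of the spread between cultures. Counts past 1.5-fold are descriptive. Moderated linear models per gene, gene set tests with preset or estimated correlation, permutation of library labels, the replicate block and leaving out replicates had been planned for values per library, and none could be run on merged columns. No p-value is given anywhere for that reason. Pol II occupancy itself could not be compared, since the table used here holds no densities.

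The 14 gene lists, the alternative settings and the rule for naming genes were fixed before the data were examined. Gene set tests had been planned for the lists, and the description by random lists was adopted only once the columns proved to be merged. Each list was described by the percentile of its median change among the medians of 10000 random lists of the same size, drawn from 20 bins of mean log2 ratio over the 4 Pol II columns (random seed 1). A list above percentile 97.5 or below 2.5 lay outside the central 95% of random lists. Random lists were not matched on gene length, which was not used here. The lists were cytosolic ribosomal proteins, ribosome biogenesis, splicing factors, Pol II pausing and elongation factors, pluripotency, lineage, p53 target, histone, immediate-early and heat shock, translation factor, mitochondrial respiratory chain, cell cycle and snoRNA host genes, and fibroblast markers for the feeder cells. Single genes were placed by their percentile among the genes of the same bin. The procedure was tested on simulated data. The changes were shuffled among the genes of each bin, and a known shift was added to random lists of 80 of the 21441 genes. With no shift, 1.67% of 60 simulated lists at 48 h and 5% at 72 h lay outside the central 95%. With a log2 shift of 0.1 these shares were 75% and 55%, and with 0.3 both were 100%. The low shares without a shift follow from the shuffling. Members of real lists may vary together, which was not simulated, so the percentiles are descriptive and not error rates.

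The planned naming rule for merged values took Htatsf1 and the 10 genes with the highest and the 10 with the lowest mean log2 change among those with the same sign at both times. From each list the rule asked for the 2 members with the smallest p. As no p exists, the 2 members with the largest mean change in either direction were taken. Because the first part of the rule picked mostly genes with ratios near or below 1, another rule was added after seeing the data. It used the 11017 genes with a mean log2 ratio of at least 2, a ratio of 4, called start-enriched here, that had the same sign at both times, and ranked them by the smaller of their changes. Other settings were pseudocounts of 0.1 and 1, no filter, genes between the 10th and 90th percentile of the mean ratio, equal medians in every group, quantile normalization, every transcript row, and only the groups of the time compared, a setting planned for the models and applied here to the filter and to the matching of random lists. Start-enriched genes alone, the last row of each gene, subtraction of the input change and matching on the input ratio were added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.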

Results

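Pol II ChIP-seq travelling ratios were compared between mouse ESCs treated with ethanol and ESCs treated with tamoxifen to delete HTATSF1, a protein known as a cofactor of transcription elongation and splicing. The question, as far as the series states it, is how Pol II occupancy of chromatin differs with and without HTATSF1. The deposited table merges the 2 libraries of each group, so every value below is the authors' merged value for a group. There is no replicate check of any difference, no difference was tested, and sequencing depth is unknown. Over 21441 genes the median travelling ratio was 3.48 after ethanol and 3.78 after tamoxifen at 48 h. At 72 h it was 5.68 after ethanol and 5.06 after tamoxifen. In the input DNA of 48 h the medians were 1.59 after ethanol and 1.67 after tamoxifen, and 0.364% and 0.467% of genes had a ratio above 4. In Pol II libraries, by contrast, 46.9% (ethanol, 48 h), 48.8% (tamoxifen, 48 h), 55.6% (ethanol, 72 h) and 54.1% (tamoxifen, 72 h) of genes were above 4.

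**Figure D1:**
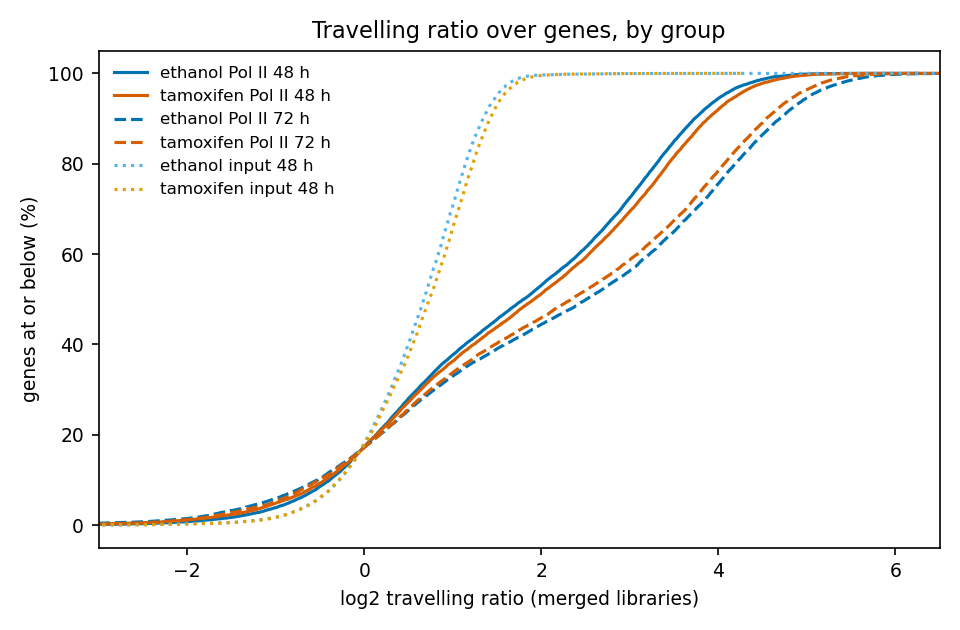
Cumulative share of genes (percent, vertical axis) by log2 travelling ratio (horizontal axis) for the 6 merged groups, with colour for treatment and line style for time and input. The input curves lie to the left, with median ratios of 1.59 and 1.67, and the 72 h Pol II curves reach highest, with medians of 5.68 after ethanol and 5.06 after tamoxifen.

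The targeted gene was looked at first. Htatsf1 had a higher travelling ratio after tamoxifen at both times. For the first listed transcript (NM_028242) it was 18.8 after ethanol and 29.0 after tamoxifen at 48 h, 1.54-fold higher, and 26.9 and 36.9 at 72 h, 1.37-fold higher. The other listed transcript (NM_029371) stood at 11.6 and 23.5 at 48 h and at 20.4 and 25.8 at 72 h. Among genes of similar ratio, the log2 changes of 0.62 and 0.45 of the first transcript lay at percentiles 99.6 and 99.7. In the input, the Htatsf1 ratio of this transcript was 2.32 after ethanol and 2.66 after tamoxifen. A ratio of start to body does not show whether the gene was deleted, and the floxed part is not given in the sources used here, so these values do not check the labels.

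At 48 h, genes of the core growth machinery had somewhat higher ratios after tamoxifen, by about as much as other genes of similar ratio, and the input ratios of several of these lists were higher as well. Among cytosolic ribosomal protein genes, 72 of 82 were higher, and the list's median ratio was 2.84 after ethanol and 3.25 after tamoxifen. Translation factor genes were higher in 40 of 42 cases, splicing factor genes in 64 of 74 and respiratory chain genes in 60 of 73. Immediate-early and heat shock genes, which respond quickly to signals and stress, were higher in 24 of 46. Eif3f, an initiation factor subunit, went from 4.98 to 6.94, and Ddx21, a nucleolar helicase, from 6.77 to 8.93. Mdm2, the ubiquitin ligase that restrains p53, went the other way, from 4.06 to 2.07.

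Over all genes at 48 h the median log2 change was 0.11 (95% interval over genes 0.11 to 0.12), and 64.4% of genes were higher after tamoxifen. By at least 1.5-fold, 2424 genes were higher and 2040 lower as deposited, but relative to the median change of all genes 1898 were higher and 2520 lower. Among the 11017 start-enriched genes, 75.6% were higher, 334 by 1.5-fold, while 61 were lower by 1.5-fold. Taken relative to the median change of the start-enriched genes themselves, 159 of them were higher by 1.5-fold and 150 lower. Setting the medians of the groups equal shifts the 48 h change by -0.12, to a median of -0.0029, and leaves 49.6% of genes higher. Changes of gene groups are therefore best read against the median of all genes.

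None of the 14 lists lay above the central 95% of random lists at 48 h. The median log2 changes were 0.17 for ribosomal protein genes (percentile 94.6), 0.16 for ribosome biogenesis (83.7), 0.17 for splicing factors (92.7), 0.19 for translation factors (94.9) and 0.18 for respiratory chain genes (94.96). Lineage genes stood at 0.19 (95.5) and snoRNA host genes at 0.19 (82.3). Histone genes stood at 0.05 (51.8), below 0 with group medians set equal. Pausing and elongation factor genes were at 0.11 (22.2), pluripotency genes at 0.09 (35.8), p53 targets at 0.10 (32.1) and fibroblast markers at 0.07 (24.1), and each of these was below 0 once group medians were set equal or the ratios were quantile normalized. Cell cycle genes were at 0.12 (44.2), below 0 with quantile normalization. Immediate-early and heat shock genes had a median of 0.01 at percentile 1.0, below the central 95%, and -0.10 with equal medians. With every transcript row used, splicing factors (97.6) and lineage genes (99.4) were above the central 95%. With only genes between the 10th and 90th percentile of ratio, no list was below it. With the input change subtracted, immediate-early genes were no longer below it (percentile 3.37) and p53 targets were, at -0.19 (percentile 0.43). The same subtraction left medians of 0.015 for ribosomal protein genes (percentile 18.9), 0.0016 for ribosome biogenesis (21.9) and 0.015 for translation factors (34.9).

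At 72 h, the ratios of ribosomal protein genes were higher after tamoxifen, and several other lists shared this. The ratios of most genes were lower as deposited, though not with equal group medians (57.1% of genes higher) or quantile normalization (52.5%). Of the 82 genes, 76 were higher after tamoxifen, and 81 were above the median change of all genes. The list's median ratio was 3.85 after ethanol and 4.48 after tamoxifen. Rps12 went from 3.00 to 4.11 and Rpl39 from 2.89 to 3.91. Genes that supply and run the ribosome went along, with 31 of 42 translation factor genes, 45 of 79 ribosome biogenesis genes and 14 of 15 snoRNA host genes higher. The snoRNA hosts, whose introns hold RNAs that guide rRNA modification, included Snhg4 (3.00 to 4.69) and Snhg3 (2.96 to 4.26).

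Other housekeeping groups were on the same side at 72 h. Splicing factor genes were higher in 57 of 74 cases, among them the U2 component gene Sf3b5 (6.54 to 11.04). Respiratory chain genes were higher in 48 of 73, including Ndufa2 (8.46 to 12.6) and cytochrome c, Cycs (7.01 to 9.85). Pausing and elongation factor genes were higher in 33 of 56, with Larp7, which binds the RNA that holds back the elongation kinase, at 9.58 after ethanol and 16.1 after tamoxifen; its 48 h input ratio was also higher, by 0.63 on the log2 scale. Ell3 of the same list went from 6.53 to 4.27. Cell cycle genes were higher in 32 of 55, with E2f1 going from 6.62 to 9.26 and the cyclin gene Ccnd3 from 4.54 to 1.56. Pabpc1, the poly(A)-binding protein gene, went from 8.01 to 11.1, and the immediate-early gene Fosl1 from 2.76 to 4.46.

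Over all genes at 72 h the median log2 change was -0.09 (95% interval over genes -0.10 to -0.09), and 40.4% of genes were higher after tamoxifen. By at least 1.5-fold, 2380 were higher and 3481 lower as deposited, and relative to the median change of all genes 2712 were higher and 2831 lower. Of the start-enriched genes, 34.2% were higher, 52 by 1.5-fold, and 957 were lower by 1.5-fold. Taken relative to the median change of the start-enriched genes themselves, 119 of them were higher by 1.5-fold and 596 lower. Setting group medians equal shifts the 72 h change by 0.17, to a median of 0.07, and leaves 57.1% of genes higher, so the sign over all genes depends on the scaling.

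Of the 14 lists, 9 lay above the central 95% of random lists at 72 h and none lay below. Ribosomal protein, splicing factor, translation factor and respiratory chain genes had medians of 0.20, 0.16, 0.15 and 0.10, each above all random lists (percentile 100). Ribosome biogenesis genes had a median of 0.04 (99.96), pausing and elongation factors 0.04 (99.8), cell cycle genes 0.06 (99.98), snoRNA hosts 0.28 (99.9) and immediate-early and heat shock genes 0.08 (99.9). The ribosomal protein median was 0.29 above that of all genes. In the start-enriched genes alone, immediate-early genes had a median of -0.01 (95.2) and the 3 snoRNA hosts left one of 0.03 (73.5). Pluripotency genes lay within the central 95% at 0.01 (96.3), with a mean of -0.08 and a median of -0.06 over every transcript row, and above it among genes between the 10th and 90th percentile of ratio (98.31) and among start-enriched genes (97.68). Lineage genes stood at -0.14 (26.7), above 0 with equal group medians and below the central 95% with every transcript row (1.34). Histone genes were higher in 9 of 60 cases, with a median of -0.20 (8.59). The p53 targets (-0.11, percentile 49.2) and the fibroblast markers (-0.13, percentile 35.8) were above 0 with equal medians, p53 targets also with quantile normalization.

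**Figure D2:**
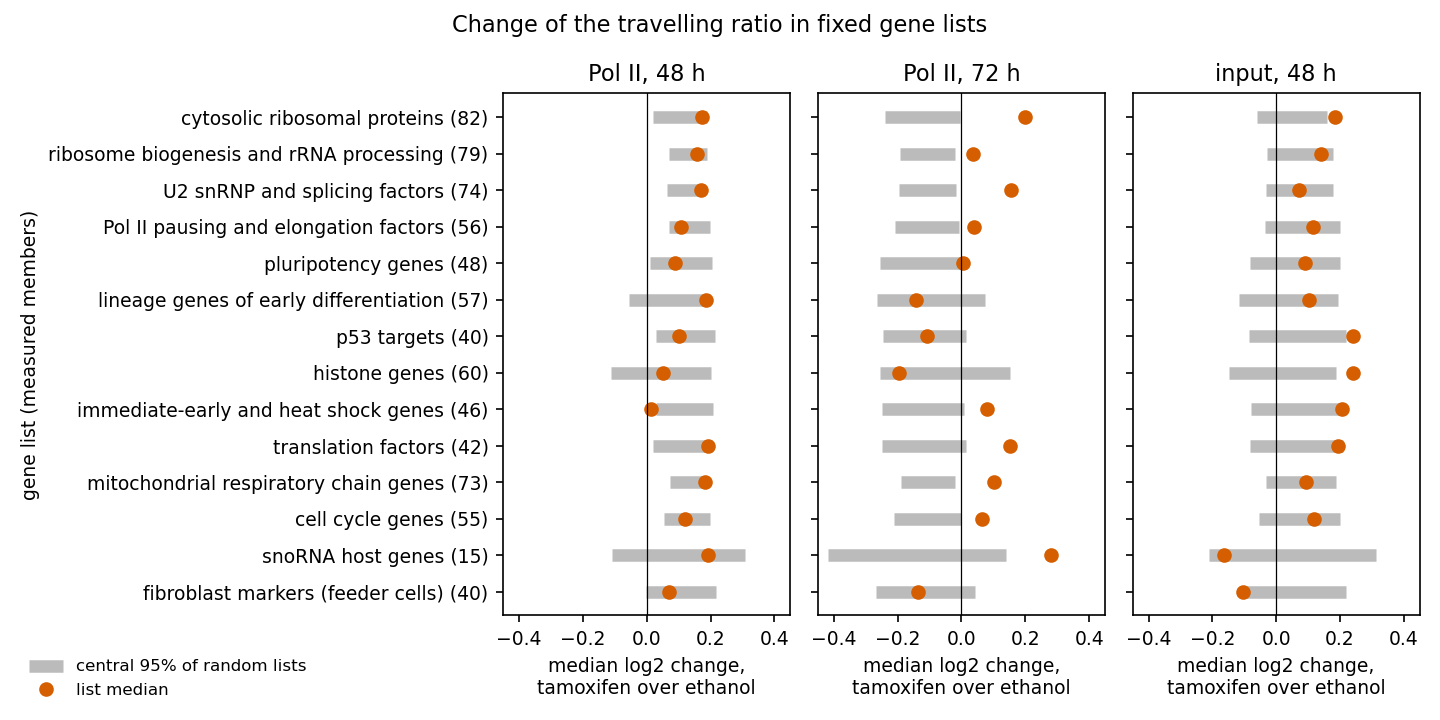
Median log2 change of the travelling ratio, tamoxifen over ethanol (horizontal axes), of 14 fixed gene lists (vertical axis, measured members in parentheses) for Pol II at 48 h, Pol II at 72 h and input at 48 h; grey bars are the central 95% of 10000 random lists of matched ratio. At 72 h 9 lists lie above their bar, among them ribosomal proteins at 0.20, while at 48 h none does and the immediate-early list, at 0.01, lies below; with equal group medians that list is at -0.10 at 48 h.

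Taking both times together, the start-enriched genes with the largest changes in the same direction were picked out, with no replicate spread to set them against. Gria3, a glutamate receptor subunit gene, went from 2.00 to 5.64 at 48 h and from 4.16 to 9.55 at 72 h. Agtr1b, an angiotensin receptor gene, went from 3.67 to 6.08 and from 6.16 to 20.8. Fbxo16, an F-box gene, went from 5.69 to 3.27 and from 14.8 to 5.39, and Fgf13 from 6.46 to 3.86 and from 11.8 to 4.97. These come from the rule added after seeing the data, which also named 4930444P10Rik, Zscan4e, Anks1b, Magee2, Tnfaip6, Arxes2, Hs6st3 and Pth2r as higher. Lower at both times were also Gm2663, Cxx1b, 3110007F17Rik, Mmp25, Edn3, the apelin gene Apln, the RNA sensor gene Ifih1 and Fam110c. The 48 h input ratios of Ifih1 and Fam110c were also lower after tamoxifen, by log2 changes of -0.74 and -1.31 beside Pol II changes of -0.71 and -0.70. The input went against the Pol II direction for Zscan4e, from 4.85 to 1.10, and for Cxx1b, by a log2 change of 1.36. Zscan4e belongs to a multicopy gene cluster, so its value is uncertain where reads are shared with near-identical copies. Anks1b had a mean log2 change of 1.21 in its first row and of -0.51 in its last, another transcript.

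Members of the fixed lists with the largest mean change were of both kinds. Mdm2 was lower at both times, from 4.06 to 2.07 and from 4.77 to 1.73, at percentiles 1.68 and 2.24 among genes of similar ratio. Cd80, listed with it as a p53 target, went from 1.80 to 3.03 and from 2.35 to 5.85. Among pluripotency genes Prdm14 went from 1.78 to 1.42 and from 3.72 to 1.98, and Dppa3 from 1.49 to 1.16 and from 1.95 to 1.36. Among lineage genes the nodal antagonist Cer1 went from 1.20 to 0.58 and from 1.65 to 0.46, and Elf5 from 0.97 to 0.79 and from 1.603 to 0.44. All of these were near or below the median input ratio of all genes. The input ratios of Elf5 itself were lower, 0.57 after ethanol and 0.95 after tamoxifen. The histone genes Hist1h2aa and Hist1h2bn went from 2.98 to 2.12 and from 16.6 to 9.53 at 72 h. The input ratio of Hist1h2bn was infinite after ethanol and after tamoxifen, so its Pol II ratios have no input level to be set beside. Col1a2, a collagen chain gene of the fibroblast list, went from 2.06 to 4.27 at 72 h, and Postn (periostin) from 1.81 to 2.67. Rrp1b, Snrpn and Jund completed the rule, with 72 h ratios after tamoxifen of 1.02, 0.16 and 0.13; the mean change of Snrpn was 0.40 in its first row and -0.01 in its last.

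The planned rule for genes with the largest mean change named genes with ratios at or below the input level in at least 1 column. Higher were 4930428E07Rik, Olfr1121, Pet2, Adam28, Vmn1r120, Vmn2r30, Olfr1448, Lce3e, Olfr532 and 5430427O19Rik. Lower were Olfr734, Olfr1043, Serpinb3a, Olfr10, Olfr629, Cd163l1, 2010005H15Rik, A330093E20Rik, H2-M2 and Olfr993. Olfr1121, an olfactory receptor gene, went from 0.25 to 0.67 at 48 h and from 1.45 to 160 at 72 h, and Olfr734 from 0.99 to 0.19 and from 1.43 to 0.0051. In the lowest decile of genes by ratio the interquartile range of the log2 change was 1.28 at 48 h and 1.55 at 72 h, against 0.20 and 0.29 in the highest decile. Over both times the median log2 change of all genes was 0.01, with 51.6% higher.

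**Figure D3:**
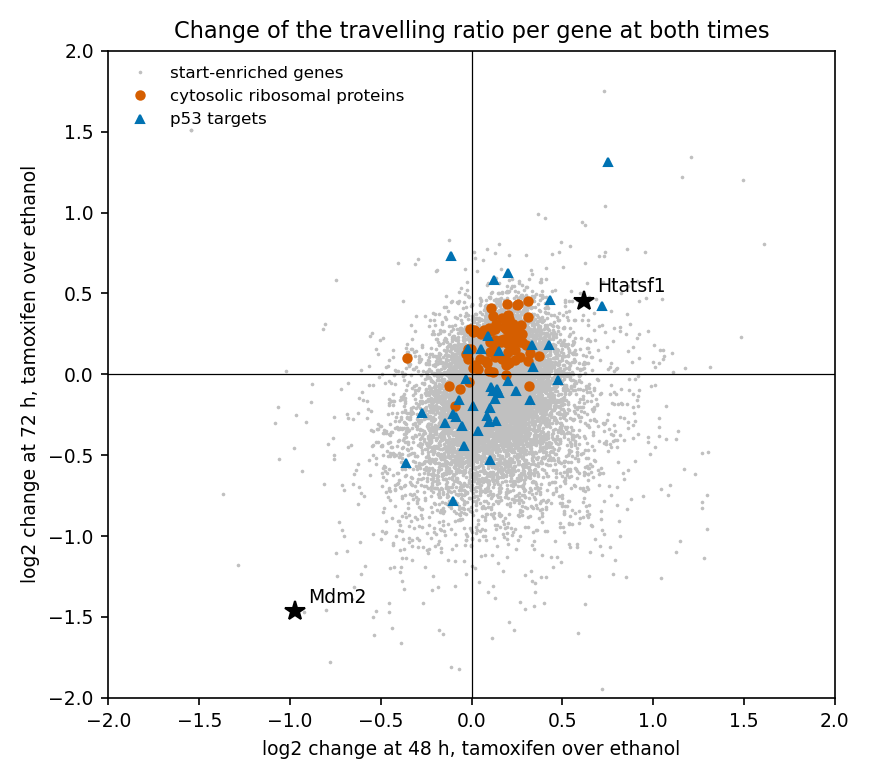
Log2 change of the travelling ratio, tamoxifen over ethanol, at 48 h (horizontal axis) and 72 h (vertical axis) for start-enriched genes (grey points; 10 lie outside the axes), all measured cytosolic ribosomal protein genes (circles), p53 targets (triangles), and Htatsf1 and Mdm2 (stars). Htatsf1 lies at 0.62 and 0.45, Mdm2 at -0.97 and -1.46, and 70 of the 82 ribosomal protein genes were higher at both times.

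Comparing the times, 70 of the 82 ribosomal protein genes were higher after tamoxifen at both. As deposited, their change differed between the times by a median of 0.04. Against the median of all genes, the list was 0.06 above at 48 h and 0.29 above at 72 h, and its 72 h change minus its 48 h change lay at percentile 100 of random lists. That difference also lay at percentile 100 for splicing factor, respiratory chain and immediate-early and heat shock genes. It lay at 99.7 for translation factors, 99.35 for ribosome biogenesis and 99.2 for cell cycle genes, and within the central 95% for the other lists. Splicing factors (49 of 74), translation factors (31 of 42) and snoRNA hosts (14 of 15) were also mostly higher at both times. Of 60 histone genes, 41 were higher at 48 h and 9 at 72 h, while 20 and 16 were above the median change of all genes. Their median difference of -0.25 lay at percentile 11.4 of random lists. The median over all genes of the 72 h change minus the 48 h change was -0.20 as deposited and 0.08 with equal group medians. Ranked over genes, the changes at 48 h and 72 h had a Spearman correlation of 0.06 (0.17 in start-enriched genes), and genes are not independent replicates. Over all genes, 582 were higher by 1.5-fold at both times and 616 lower, against 507 and 515 if the times were independent within deciles of ratio. Of the start-enriched genes, 14 were higher at both times against 2.76 on the same reckoning, and 28 were lower against 8.17. Relative to the median change of the start-enriched genes themselves, 14 were higher against 3.00 and 42 lower against 13.6. The reckoning treats the genes of a decile as equally variable, so an excess need not be a shared effect. By their labels the 72 h libraries carry the same barcodes as libraries of 48 h, which points to separate sequencing; no label states the batches, and any batch difference would coincide with time.

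**Figure D4:**
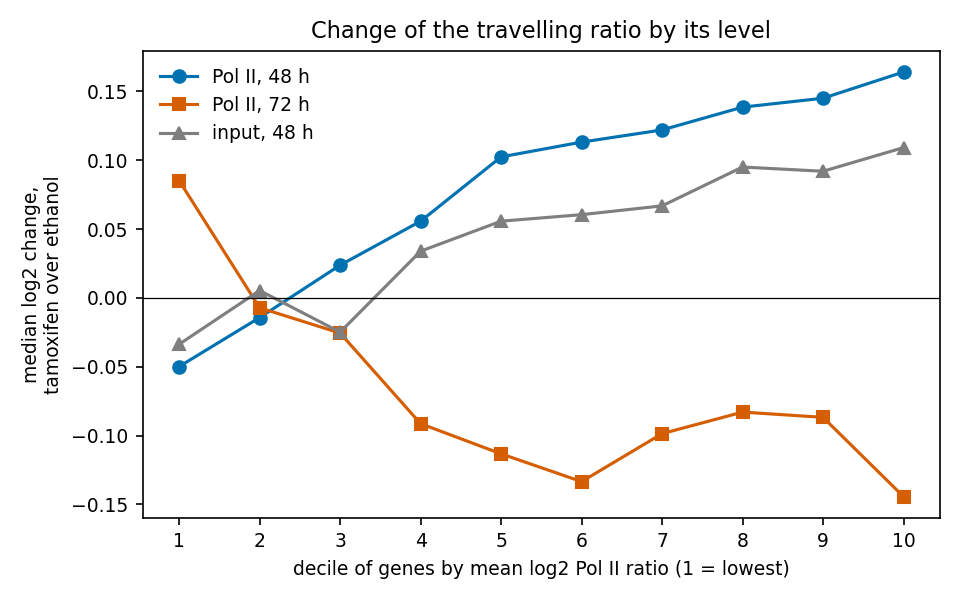
Median log2 change of the travelling ratio, tamoxifen over ethanol (vertical axis), in deciles of genes by mean log2 Pol II ratio (horizontal axis, 1 is lowest) for Pol II at 48 h, Pol II at 72 h and input at 48 h. From the lowest to the highest decile the median went from -0.05 to 0.16 at 48 h and from 0.09 to -0.14 at 72 h.

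Among ethanol controls, the ratios of most genes were higher at 72 h than at 48 h. Ribosomal protein genes had a median ratio of 2.84 at 48 h and 3.85 at 72 h, respiratory chain genes 7.50 and 11.9, and pluripotency genes 4.01 and 5.53. Over all genes the median log2 difference was 0.65, or 1.57-fold, with 79.4% higher at 72 h, and 98.7% of start-enriched genes were higher. As deposited, this difference between control groups was larger than the median change with tamoxifen at either time, and with equal group medians it was -0.05.

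In the input DNA, ribosomal protein genes also had higher ratios after tamoxifen, 1.55 against 1.72 in the median, with a log2 change of 0.18 at percentile 99.4. Histone genes (0.24, percentile 99.5), p53 targets (0.24, percentile 98.7) and immediate-early genes (0.21, percentile 97.6) were above the central 95% of random lists in the input as well, and fibroblast markers (-0.10, percentile 2.31) below. Splicing factors (0.07, percentile 49.8) and snoRNA hosts (-0.16, percentile 5.56) were within it. Over all genes the input change had a median of 0.06, and its Spearman correlation with the 48 h Pol II change was 0.02 across genes.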

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

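The gene lists were fixed before the data were examined. The tests that weigh explanations here were chosen after seeing the data, and all but the subtraction of the input change after seeing the results they bear on. The median log2 change over all genes was above 0 at 48 h and below 0 at 72 h, a difference of medians of -0.21 that was not tested, because each group has 1 merged column. With equal group medians the signs turned, to -0.0029 at 48 h and 0.0727 at 72 h. It drew attention since the same contrast pointed opposite ways at the times. A candidate explanation is that the merged libraries differ in ChIP enrichment, with a change that grows with the ratio: the highest decile of genes differed from the lowest by -0.23 at 72 h and by 0.21 at 48 h, but at 72 h decile 4 (median ratio 1.819) was already at -0.09, like deciles 7 to 9, and the input, which is not enriched, differed by 0.14, so this stays open. A background shift as the whole of the 48 h change was left open, as the median with the input change subtracted was 0.04 (0.0378, with 95% bounds over genes of 0.0298 and 0.0459). An effect of the deletion that turns between the times cannot be told apart from these, since any sequencing batch would coincide with time and no replicate values are given.

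Lineage genes differed between the times by -0.33, with medians of 0.19 at 48 h and -0.14 at 72 h. The histone genes differed by -0.25, from 0.05 to -0.20. For p53 targets the difference was -0.21 (0.10 and -0.11), and for the fibroblast markers -0.20 (0.07 and -0.13). None of these could be tested against replicates. Among random lists of matched ratio, the 72 h minus 48 h change lay at percentile 4.42 for lineage genes, 11.4 for histone genes, 46.8 for p53 targets and 18.1 for fibroblast markers, all within the central 95%. With every transcript row, lineage genes lay outside it at each time, at percentile 99.4 at 48 h and 1.34 at 72 h. With equal group medians lineage genes, p53 targets and fibroblast markers were above 0 at 72 h.

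Ribosomal protein genes at 72 h went against most genes as deposited; with equal group medians 57.1% of genes, and with quantile normalization 52.5%, were higher too, and the list's median was then 0.364 and 0.316. Their level of ratio is argued against as the cause, since the list lay at percentile 100 of random lists of the same ratios. Weaker enrichment in the tamoxifen libraries would draw ratios down, yet the lower 95% bound of the list's median was 0.15, with an upper bound of 0.25. This holds for ratios as deposited, whose normalization is not explained, and the bounds describe scatter over genes only. Random lists were matched on the ratio and not on density over the gene body, so a difference in enrichment is not excluded. Gene length was not matched either, so a link of the change to length is not excluded. A change of the DNA background at these genes stays open: the list lay at percentile 99.4 in the 48 h input, with a median of 0.18, and no input at 72 h was analysed here. An effect of deleting HTATSF1 on these genes also stays open, untested for lack of replicate values.

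Htatsf1 itself had higher ratios after tamoxifen at both times. Scatter of single genes is argued against, as the changes lay at percentiles 99.6 and 99.7 among genes of similar ratio. If deleted DNA were missing from the gene body, the input ratio would be higher too; the input log2 change was 0.20 for the first transcript and -0.08 for the other, beside Pol II changes at 48 h of 0.62 and 1.02. Set against the interquartile range of 0.47 of the input at similar genes, the gap was larger for the other transcript and smaller for the first, which keeps this open for the first transcript. Loss of transcript elongation on the deleted allele was not tested.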

How the results depend on the processing

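No paired analysis was possible because the deposited columns merge the replicates, and for the same reason leaving out replicates, the model variants, gene set tests with an estimated correlation and occupancy alternatives were not run. Depth limits cannot be stated without counts. Start-enriched genes alone, the last row per gene, input subtraction and matching on the input ratio were chosen after seeing the data. The sign of the ribosomal protein median held under every setting run. The sign of the all-gene medians held under every setting but the 2 scalings, which remove most of a shift over all genes by construction. Against other genes, the ribosomal list at 48 h went from percentile 94.6 of random lists to 18.9 with the input change subtracted, with a median below that of all genes. Equal medians gave -0.00287 at 48 h, 0.0727 at 72 h, 0.0354 over both times, 0.0829 for the difference of times and -0.0522 between ethanol groups. Quantile normalization gave 0.00111, 0.0244, 0.0166, 0.0335 and -0.0253. The cause of the differences below was not tested unless the setting itself gives it. Without a filter (pseudocount 0.1) the all-gene medians were 0.108 at 48 h, -0.0840 at 72 h, -0.189 for their difference and 0.620 between ethanol groups. On the same genes, a pseudocount of 0.1 gave 0.637 between ethanol groups, and a pseudocount of 1, which shrinks low ratios, gave 0.0892, -0.0716, 0.00655 over both times, -0.162 and 0.518. Between the 10th and 90th percentile the difference of times was -0.193, and 0 lists lay below random lists at 48 h. Start-enriched genes alone gave 0.139, -0.110, 0.0156, -0.240 and 0.840, ribosomal proteins 0.204 at 48 h, and immediate-early genes -0.0108 at 72 h. With every transcript row the ethanol groups differed by 0.668, 2 lists lay above random lists at 48 h (splicing factors and lineage genes) and 1 below at 72 h (lineage genes), and pluripotency genes had -0.0634 at 72 h. Subtracting the input gave 0.0378 at 48 h, ribosomal proteins 0.0147, p53 targets -0.188 (percentile 0.43 of random lists), histones -0.120, immediate-early genes -0.111 and cell cycle genes -0.0267. Equal medians gave ribosomal proteins 0.0565 at 48 h and 0.364 at 72 h. They also turned, at 48 h, elongation factors (-0.00963), pluripotency (-0.0284), p53 (-0.0154), histone (-0.0674), immediate-early (-0.105) and fibroblast genes (-0.0488) and, at 72 h, lineage (0.0222), p53 (0.0568) and fibroblast genes (0.0307). Quantile normalization gave ribosomal proteins 0.0714 and 0.316. It turned, at 48 h, elongation factors (-0.0186), pluripotency (-0.0198), p53 (-0.0308), immediate-early (-0.108), cell cycle (-0.0101) and fibroblast genes (-0.0215) and, at 72 h, p53 targets (0.0280). The last row of a gene gave mean changes of -0.509 for Anks1b and -0.0123 for Snrpn. At 72 h, 9 lists lay above random lists with matching on the input ratio too. Ribosomal protein, biogenesis, splicing, elongation, translation, respiratory chain and cell cycle lists did so under all 11 settings that gave percentiles at 72 h. These 11 count the main setting, and also equal medians, which cannot change a percentile. Subtraction of the input change was not possible at 72 h. Of 500 recomputed values of named genes 436 stayed close, 62 moved and 2 turned. Of 273 values of the lists other than ribosomal proteins 214 stayed close, 37 moved and 22 turned. These counts do not measure how stable the values are. A setting that only leaves out genes, such as that between the 10th and 90th percentile, cannot change the value of a gene it keeps. The last row cannot change a gene with a single row. The margin for staying close was also wide for some genes: Jund counted as close with a mean change of -0.420 in the main setting and -0.0578 with a pseudocount of 1.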

Other observations

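The tests in this part were chosen after the results were seen. Gene families were formed by the letters a symbol starts with, leaving out the fixed lists, and 85 families had at least 20 genes. At 72 h the collagen family, 37 genes outside the fibroblast list, had a median log2 change of -0.40 (percentile 0.06), and semaphorins, guidance molecules, one of -0.43 over 20 genes (percentile 0.23). Examples, chosen after their values were seen, are Col4a2, from 14.4 after ethanol to 8.29 after tamoxifen, Col5a3, from 19.7 to 8.82, and Sema5a, from 32.6 to 15.3. At 48 h these families stood at 0.10 (percentile 43.4, below 0 with equal group medians) and 0.07 (24.2, below 0 with either scaling). Tbc genes, many of them for Rab GTPase regulators, had -0.32 over 28 genes (percentile 0.16), against 0.07 at 48 h (6.34, below 0 with either scaling). At the upper end were zinc finger genes of the Zfp family, at -0.03 over 349 genes (percentile 99.99) and above 0 with equal group medians or quantile normalization, keratin-associated Krtap genes, at 0.47 over 34 genes with a median ratio of 0.98 (percentile 99.2; -0.01 at 48 h, above 0 with quantile normalization), mitochondrial ribosomal proteins of the Mrpl family, at 0.07 over 47 genes (percentile 99.95), and nucleoporins, at 0.06 over 22 genes (percentile 98.35). Collagens, semaphorins, Tbc, Krtap, Mrpl and nucleoporin genes had the same sign at 72 h with equal group medians and with quantile normalization. In all, 4 families lay above the central 95% of random lists at 72 h and 8 below it. By chance 2.12 would be expected at each end, if the members of a family varied independently. At 48 h the counts were 0 and 3. At both times they were 0 and 1, the latter being genes whose symbols start with Sh (percentile 1.69 at 48 h and 0.36 at 72 h). Claudins stood at -0.30 over 24 genes at 48 h (percentile 0.23) and at percentile 39.6 at 72 h.

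Mdm2 was lower at both times, and a hypothesis is that p53 target genes in general are lower by about as much. The other 39 listed p53 targets had a median log2 change of -0.10 at 72 h (95% bounds over genes -0.24 and 0.05) and 0.10 at 48 h. For Mdm2 the changes were -1.46 at 72 h and -0.97 at 48 h. Mdm2 was named for having the largest mean change of its list, so a smaller median of the others was largely built in. The size of the gap depends on that choice too, and no conclusion is drawn from it. The median of the others at 72 h, with bounds that do not reach the change of Mdm2, argues against a change that large across the list. A smaller change of the list stays open. With the input change subtracted, the p53 list including Mdm2 had a median of -0.19 at 48 h, at percentile 0.43 of random lists. Without subtraction the list stood at 0.10 (percentile 32.1), and in the input itself at percentile 98.7. The low value thus came with the subtraction of a high input change. The input ratio of Mdm2 was higher after tamoxifen, by 0.27. Whether Mdm2 alone differs between cultures cannot be judged from merged columns.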
